A study of Mus musculus with 14 samples.

How the data were processed

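Total RNA from dissected lungs of mice at postnatal day 6 was measured on 14 Affymetrix mouse Gene ST version 1 arrays, with 100 ng of RNA per array. Per the labels, the arrays formed 4 groups: 4 Atxn1l knockouts with 4 wild-type controls, and 3 Atxn1 knockouts with 3 wild-type controls, all on C57BL/6J. Mice came from intercrosses of heterozygotes, collected as pairs of a wild type and a knockout, and the labels do not say which arrays form a pair. The deposited values are log2 RMA levels, made by the authors with RMA (background correction, quantile normalization and median polish) over the 8 arrays of the Atxn1l knockouts and their controls and, separately, over the 6 arrays of the Atxn1 knockouts and their controls. Each value is the level of a probe set built for 1 Entrez gene. The version of the probe set definition is not given in the sources used here. The table held 21212 probe sets, of which 18786 had 1 gene symbol, 6 had several and 2420 had none in the platform's gene table. Work by gene used 1 probe set for each of 18784 genes.

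Because these sets of arrays were normalized apart, each knockout was compared with its own wild types on its own arrays. Changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, no covariate), as knockout minus wild type on the log2 scale, two-sided, for all 21212 probe sets. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The difference between the knockouts was the contrast of both effects in 1 limma fit of the 14 arrays with 4 group means. Standard errors of single genes are those of the limma fit. Those of list means come from the spread of the mean between arrays within both groups, or, with the Xist covariate, from an ordinary linear fit. SD is the spread between arrays of a group. Beside the excess of 1 array it is the spread over the other arrays of its set, knockouts and wild types together.

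The comparisons, tests, named genes and 52 gene lists (lung cell types, tissues a dissection can carry along, and pathways) were fixed before the data were examined. Of 859 list memberships, 797 were matched to a measured gene. Lists were tested with limma's camera at an inter-gene correlation of 0.01, with the Benjamini-Hochberg adjustment over the 52 lists of a comparison. Camera with the correlation estimated per list and fry were run beside it. An exact two-sided permutation test of each list's mean per array was added after seeing the data. Its smallest possible p is 0.0286 for 4 against 4 arrays and 0.1 for 3 against 3, so it cannot reach 0.05 in the Atxn1 set. In the Atxn1l set a list could pass after adjustment only if most of the 52 lists lay at that smallest p. Members of a list were counted as passing over all probe sets and, in addition, adjusted over the list alone. The genes named were Atxn1, Atxn1l and Cic, all genes past the threshold (at most 10 in each direction), up to 4 members of smallest p of each list past the threshold in either comparison and of the Capicua and metalloproteinase lists, and, where fewer than 5 genes passed, the 5 of smallest p in each direction. From the lists below the strongest 5 of a comparison, fewer members are named. Gene neighbourhoods used the order of genes in the mouse assembly GRCm38.p6, and genes within 10 Mb of a targeted gene were compared with all others by Fisher's exact test, two-sided.

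The number of arrays limits the precision, and the p of limma, fry and the permutation tests rest on the spread between these samples. Camera at a preset correlation weighs the genes of a list against other genes, and Fisher's test counts genes. Their p values do not measure the spread between mice. The labels do not state the litter or sex of a mouse. The limma and camera steps were tested on simulated data with the same numbers of arrays and independent noise for each gene. There limma recovered 58 of 67 genes with a log2 change of 0.5 at 4 against 4 arrays and 47 of 67 at 3 against 3. The simulation held no correlation between genes, outlying array or sex difference, so its recovery need not hold for these arrays. Alternatives covered a term for the replicate number, the eBayes prior, array weights, a filter on dim probe sets, joint quantile normalization, median centring, cyclic loess, thresholds, sex-linked genes, the choice of probe sets and leaving out each array. A covariate for the Xist level was added after seeing the data. Changes in splicing and single cells were not analysed here.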

Results

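Ataxin-1 and ataxin-1-like are related proteins that bind the transcriptional repressor Capicua, and the arrays ask which lung transcripts change when either is lost. Transcript levels were compared in whole lungs of 6-day-old mice: 4 Atxn1l knockouts against 4 wild types and 3 Atxn1 knockouts against 3 wild types. Levels on each array correlated across genes with those on the closest other array of its set, the Atxn1l or the Atxn1 knockouts with their controls, at r of 0.994 to 0.998. Median log2 levels were 8.44 to 8.53 in the Atxn1l set and 9.21 to 9.24 in the Atxn1 set, an offset between the separately normalized sets that leaves comparisons within a set untouched. Xist, transcribed from the inactive X chromosome of females, was low on 1 of 4 Atxn1l knockout arrays and 2 of 4 of their controls, and on 1 of 3 Atxn1 knockout arrays and 2 of 3 of their controls. The sexes were therefore unevenly spread over the groups. The low Atxn1l knockout array was replicate 1 (7.04), and replicate 3 was the only high Atxn1 wild type (13.04). Leaving out either array also removes the only mouse of that sex in its group.

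In lungs without Atxn1l, genes of macrophages and the Capicua target Etv4 were among the 5 genes that rose, and 4 fell, the deleted gene included. Chil3, a chitinase-like protein secreted by macrophages, was 2.75-fold higher, at a log2 level of 7.50 ± 0.38 (SD, n = 4) against 6.04 ± 0.17 (SD, n = 4). Msr1, the macrophage scavenger receptor, rose 1.62-fold, from 8.28 ± 0.11 to 8.97 ± 0.12 (SD, n = 4 each). Pla2g7, the plasma hydrolase of platelet-activating factor, rose 1.88-fold. Etv4, a transcription factor of the ETS family, rose 1.40-fold, from 7.94 ± 0.04 to 8.42 ± 0.06 (SD, n = 4 each).

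The targeted gene fell most: Atxn1l changed by -2.58 (SE 0.09, adjusted p = 1.18e-06), a 5.99-fold lower level. Besides it, 5 of the 21212 probe sets were higher and 3 lower at an adjusted p under 0.05, and in each of them all 4 knockout arrays lay beyond all 4 wild types. The log2 changes upward were 1.46 for Chil3 (SE 0.16, adjusted p = 0.0210), 0.91 for Pla2g7 (SE 0.12, adjusted p = 0.0497), 0.69 for Msr1 (SE 0.08, adjusted p = 0.0197), 0.59 for Hal, which starts histidine breakdown (SE 0.07, adjusted p = 0.0344), and 0.48 for Etv4 (SE 0.05, adjusted p = 0.0130). Lower levels were found for Macc1, a regulator of the Met receptor gene (-0.63, SE 0.07, adjusted p = 0.0234), Chst4, a sulfotransferase of L-selectin ligands (-0.59, SE 0.05, adjusted p = 0.00787), and Cd209a, a lectin of dendritic cells (-0.58, SE 0.07, adjusted p = 0.0253). Atxn1 differed by 0.08 (SE 0.05, adjusted p = 0.726) and Cic, which encodes Capicua, by 0.14 (SE 0.05, adjusted p = 0.527). At an unadjusted p under 0.05 there were 1802 probe sets, 964 higher and 838 lower, where 1061 would be expected by chance. Entrez gene numbers are 52335 for Atxn1l, 12655 for Chil3, 27226 for Pla2g7, 20288 for Msr1, 15109 for Hal, 18612 for Etv4, 238455 for Macc1, 26887 for Chst4 and 170786 for Cd209a. The number of changed probe sets ranged from 2, without knockout replicate 4 or wild type replicate 2, to 25, without wild type replicate 4. Atxn1l and Chst4 passed in all 8 fits without 1 array, Etv4 in 5, Chil3, Macc1 and Cd209a in 4, Msr1 and Hal in 3 and Pla2g7 in 2. With the replicate number as a block, 2 passed, Atxn1l and Chil3, though the labels do not tie that number to the collected pairs.

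**Figure D1:**
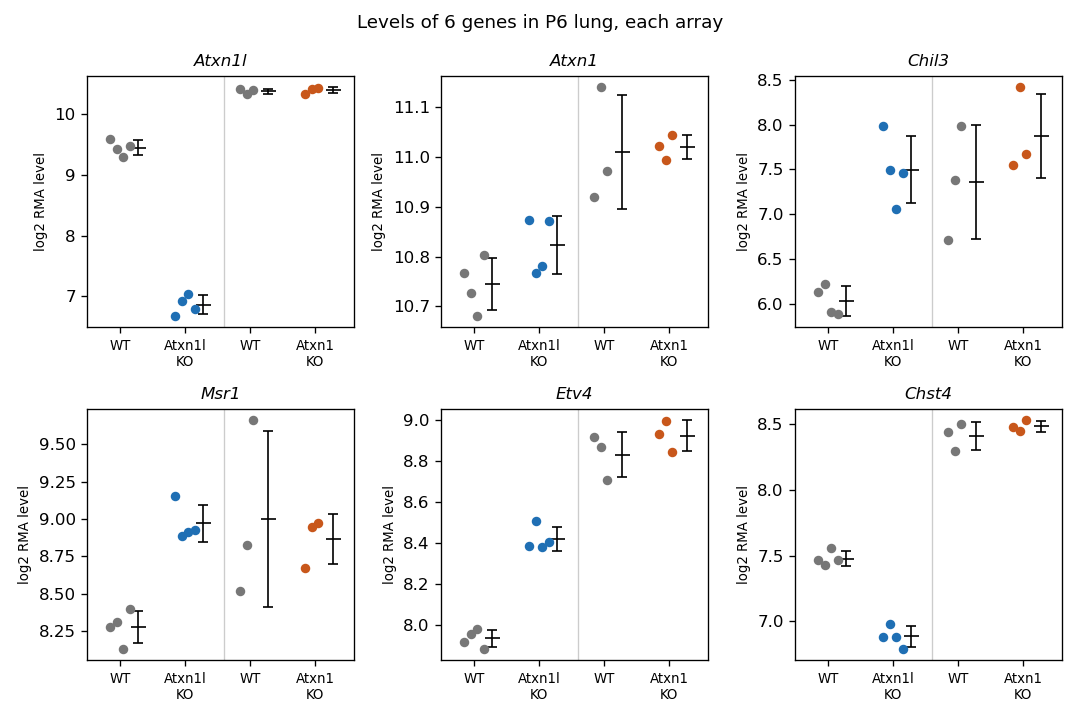
Log2 RMA levels of 6 genes on each array (points) of the 4 groups, with the mean and SD beside them. The 2 sets were normalized apart, so levels compare only within a set. In the Atxn1l set, Chil3, Msr1 and Etv4 lie higher and Atxn1l and Chst4 lower on all 4 knockout arrays than on all 4 wild types. The axis ranges differ between panels.

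Of 21 measured interferon-stimulated genes, all 21 had a log2 change above 0 in the Atxn1l knockout, with a median of 0.41, and 14 rose adjusted over the list alone, while none passed over all genes (camera adjusted p = 5.36e-16). The adjusted p was 0.878 with an estimated correlation, and 2 of 4 knockout arrays had a list mean above all wild types. Members that rose on the list alone included Oas2, an enzyme of antiviral RNA decay (0.71), Zbp1, a nucleic acid sensor (0.45), Mx2 (0.41) and Oas1a (0.28). Of 21 macrophage genes, 17 were above 0, with a median of 0.25, 9 rose adjusted over the list alone and 1, Chil3, over all genes (camera adjusted p = 7.29e-08). With an estimated correlation the adjusted p was 0.878. All 4 knockout arrays had a higher macrophage mean than every wild type (exact permutation p = 0.0286, the smallest these arrays can give, adjusted p = 0.405). Among those that passed on the list alone were the complement subunits C1qb (0.85, SE 0.15) and C1qc (0.77) and the growth factor receptor Csf1r (0.48). The array of Atxn1l knockout replicate 1 stood apart here: without it the macrophage mean was higher by 0.24 (SE 0.04), against 0.36 with it, the median fell to 0.11, and C1qb (0.67, adjusted p = 0.00299) and C1qc (0.58, adjusted p = 0.00960) passed over all genes.

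Neutrophil and granule genes lay above 0 in 20 of 20 members, with a median of 0.65, and 2 rose adjusted over the list alone, none over all genes (camera adjusted p = 3.16e-09). Its adjusted p was 0.878 with an estimated correlation, and 2 of 4 knockout arrays lay above all wild types. Values included 1.41 for Ngp and 1.20 for Ltf, both proteins of neutrophil granules, and 0.49 for Lcn2. Atxn1l knockout replicate 1 had a mean neutrophil level of 10.09, and the other arrays of that set lay between 8.14 and 8.93. Without it the mean of the neutrophil list was higher by 0.37 (SE 0.18), against 0.70 (SE 0.37) with it, and Lcn2 had 0.31. Inflammatory cytokines and chemokines were above 0 in 22 of 23 members, with a median of 0.21 and 1 passing adjusted over the list alone, none over all genes (camera adjusted p = 1.98e-05, and adjusted p = 0.878 with an estimated correlation). Examples were 0.71 for Ccl9, 0.39 for Tnf and 0.32 for Ccl2. Without knockout replicate 1 the mean of this list was higher by 0.10 (SE 0.04), against 0.23 with it, and Tnf had 0.23. Monocyte and dendritic cell genes were above 0 in 14 of 17, with a median of 0.11. On the list alone 4 rose and 1, Cd209a, fell, and over all genes 0 rose and Cd209a fell (camera adjusted p = 0.00693, and adjusted p = 0.878 with an estimated correlation). Xcr1, a receptor of cross-presenting dendritic cells, had a value of 0.47, and the list's adjusted p was 0.183 without knockout replicate 4 and 0.0713 without wild type replicate 1. All 7 platelet genes were above 0, with Ppbp at 0.55 and Pf4 at 0.44, and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.00185, and adjusted p = 0.878 with an estimated correlation). Their mean was higher by 0.26, and by 0.12 (SE 0.07) without knockout replicate 1, where Ppbp had 0.29 and Pf4 0.23.

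Cell cycle genes were above 0 in 24 of 25 members, with a median of 0.15 and none passing over all genes or adjusted over the list alone (camera adjusted p = 7.34e-06, and adjusted p = 0.899 with an estimated correlation). Values were 0.27 for the mitotic kinase Aurkb and 0.23 for the replication factor Mcm2. Knockout replicate 1 stood apart here too: without it the mean of the list was higher by 0.06 (SE 0.10), against 0.15 (SE 0.12) with it, its camera adjusted p was 0.0260 and Aurkb had 0.17. Without knockout replicate 2 the mean was higher by 0.23 (SE 0.11). Laminins and nidogens of the basement membrane were above 0 in 16 of 17, with a median of 0.09 and 1 passing adjusted over the list alone, none over all genes (camera adjusted p = 0.00556), with Lama1 at 0.46 and Hspg2 at 0.19. Elastic fibre genes were above 0 in 14 of 18, with a median of 0.08 and none passing either way (camera adjusted p = 0.00824), and Fbln2 had 0.35 and Lox 0.22. Without knockout replicate 1 the medians of these lists were 0.12 and 0.12, against 0.17 and 0.13 without wild type replicate 1. Without knockout replicate 1 Lox had 0.14, and Lama1 passed over all genes (0.51, adjusted p = 0.0425). For both lists the adjusted p was 0.899 with an estimated correlation. Hypoxia and glycolysis genes (15 of 19 above 0, median 0.07, camera adjusted p = 0.0209) and cholesterol synthesis genes (13 of 15 above 0, median 0.07, camera adjusted p = 0.0253) passed as lists with no member past either threshold. Their adjusted p was 0.878 and 0.899 with an estimated correlation. Of the 8 fits without 1 array, 5 kept the call for each of the basement membrane, elastic fibres and hypoxia and 4 for cholesterol synthesis, with the highest adjusted p at 0.266 for the basement membrane and 0.0822 for hypoxia without wild type replicate 3, 0.224 for elastic fibres without wild type replicate 2 and 0.200 for cholesterol synthesis without knockout replicate 1. Collagens (adjusted p = 0.169), alveolar type 2 cells (adjusted p = 0.597), alveolar type 1 cells (adjusted p = 0.705), endothelial cells (adjusted p = 0.168) and erythroid cells (adjusted p = 0.757) did not pass. Collagens did pass without knockout replicate 1 (mean 0.08 against 0.04 with it, camera adjusted p = 0.00174) or wild type replicate 1 (camera adjusted p = 0.00421). Endothelial genes passed as lower without knockout replicate 2 (camera adjusted p = 0.0391), wild type replicate 2 (camera adjusted p = 0.0166) or wild type replicate 3 (camera adjusted p = 0.0117).

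Capicua targets and feedback genes of the ERK pathway were above 0 in 15 of 21 members in the Atxn1l knockout, with a median of 0.04. Etv4 rose over all genes and was also the 1 member passing adjusted over the list alone (camera adjusted p = 0.0253, and adjusted p = 0.878 with an estimated correlation). Without knockout replicate 2 the adjusted p was 0.295, without knockout replicate 4 it was 0.113 and without wild type replicate 3 it was 0.263. Ccnd1 had a value of 0.14, Spred3 of 0.13 and Ccnd2 of 0.11. Matrix metalloproteinases, which degrade extracellular matrix, were above 0 in 13 of 20, with a median of 0.06 and none passing over all genes or adjusted over the list alone (camera adjusted p = 0.0596, and adjusted p = 0.878 with an estimated correlation). Values were 1.34 for Mmp8 (SE 0.41) and 0.74 for Mmp9, both stored in neutrophil granules, and 0.27 for Mmp12 of macrophages. Without knockout replicate 1 Mmp8 had 0.87 and Mmp9 0.37, and the list passed (camera adjusted p = 0.0254). Capicua targets and metalloproteinases were subjects of the study itself, so the counts adjusted over these lists alone are no independent evidence of direction. In all, 12 of 52 lists passed in the Atxn1l knockout, all upward, and 21 of the 35 splits of these 8 arrays gave as many. No list passed with an estimated correlation, and none by the permutation test, which these arrays could hardly pass after adjustment. The fry test called 1, the Atxn1 and Capicua complex itself, as lower (median 0.06, mean -0.23, with the deleted gene among its members).

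**Figure D2:**
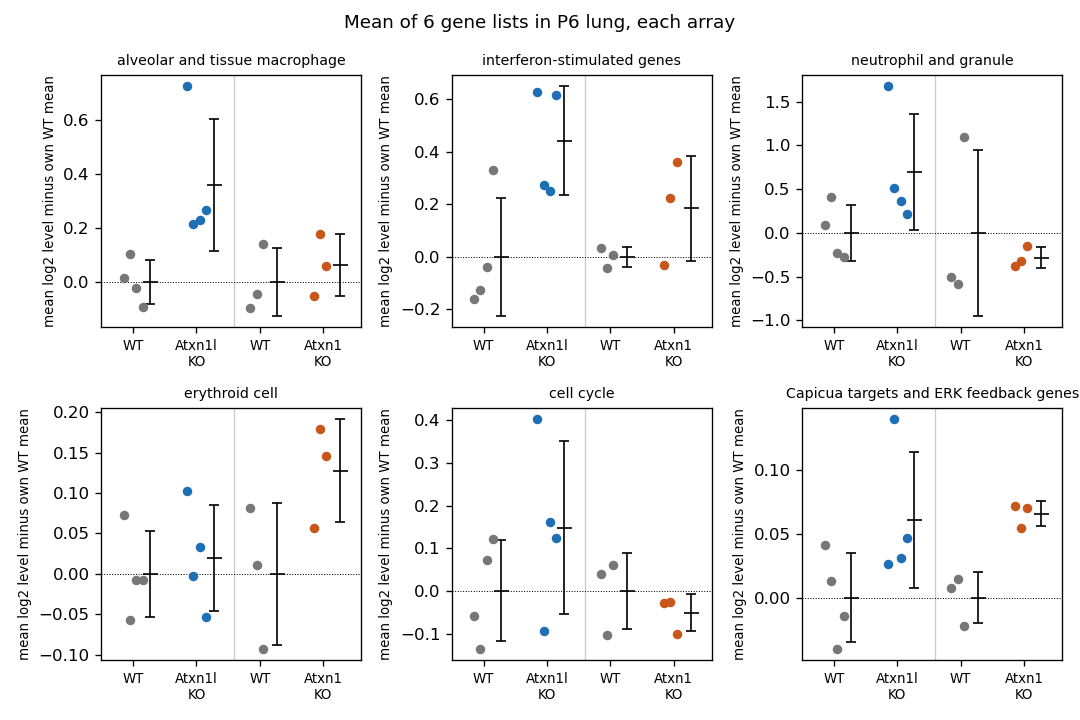
Mean log2 level of the measured genes of 6 lists on each array, minus the mean of that array's own wild types, with the group mean and SD beside the points. Macrophage genes were higher on all 4 Atxn1l knockout arrays than on their 4 wild types, and replicate 1 was highest for macrophage, neutrophil and cell cycle genes. The axis ranges differ between panels.

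Chst4 lies 5 named genes away from Atxn1l in GRCm38.p6. Within 10 Mb of Atxn1l, 1 of 183 genes had changed, Chst4, against 7 of 18591 elsewhere, the targeted gene left out (odds ratio 14.6, Fisher's exact p = 0.0754). Hp, the haemoglobin-binding haptoglobin, lies 5 named genes away on the other side and had a value of 0.54 (adjusted p = 0.192). Around Atxn1, 0 of 140 genes and 0 of 18634 others passed, so this test could show nothing there. At an unadjusted p under 0.01 there were 2 of 140 against 34 of 18634 (Fisher's exact p = 0.0295). That p was 0.109 within 5 Mb and 0.0950 within 20 Mb.

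Lungs without Atxn1 showed no single gene past the threshold. Interferon-stimulated, erythroid and Capicua target genes lay on balance slightly above their wild types, with list medians of 0.13, 0.10 and 0.05 (3 arrays against 3). Single arrays moved these sizes: the interferon median was 0.26 without knockout replicate 1 and 0.07 without knockout replicate 3, the erythroid median 0.06 without wild type replicate 3 and the Capicua median 0.08 without wild type replicate 1. Camera at the preset correlation kept the calls of these lists in all 6 fits without 1 array (highest adjusted p = 0.000547, 0.00617 and 0.0179). With an estimated correlation none of them passed. Neutrophil and cell cycle genes had medians of -0.26 and -0.05, which rested on wild type replicate 3: without it the neutrophil median was 0.23 and the cell cycle list no longer passed (median -0.02, adjusted p = 0.560). Nor did the cell cycle list pass without knockout replicate 3 (adjusted p = 0.168). Without wild type replicate 1 or 2 the neutrophil median was -0.50 or -0.58 and the cell cycle median -0.03 or -0.11.

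limma called 0 of 21212 probe sets in the Atxn1 knockout (smallest adjusted p = 0.999886). An unadjusted p under 0.05 was found for 258, 159 higher and 99 lower, where 1061 would be expected by chance. Array weights in limma called 1, Fgfbp1. That fit rests mostly on wild type replicate 3, with a weight of 6.38 against 0.16 and 0.46 for wild type replicates 1 and 2. The 5 higher genes of smallest p, none past the threshold, were Fgfbp1, a carrier of fibroblast growth factors (0.42, SE 0.06), H2-Q6, an MHC class I gene (0.68), Cybrd1, an iron reductase (0.36), Flvcr2 (0.31) and Pla2g1b (0.24). The 5 lower ones were Aoc1 (-0.55), Ssr1 (-0.28), Olfr744 (-0.26), Vmn2r61 (-0.21) and Kbtbd6 (-0.20), also without passing. Atxn1 itself differed by 0.01 (SE 0.07), at 11.02 ± 0.02 in the knockouts and 11.01 ± 0.11 in the wild types (SD, n = 3 each). Its probe set can lie outside the deleted part, so the value does not test the genotype. Atxn1l differed by 0.02 and Cic by 0.05. The array of wild type replicate 1 of this set stood apart on the first principal component, which held 46.7% of the variance.

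Interferon-stimulated genes were above 0 in 18 of 21 members in the Atxn1 knockout (camera adjusted p = 6.22e-09), with Gbp3 at 0.51, Oasl2 at 0.39, Ifit3 at 0.38 and Usp18 at 0.32. Erythroid genes were above 0 in 9 of 11 (camera adjusted p = 2.81e-05), with the band 3 anion exchanger Slc4a1 at 0.35, Epb42 at 0.28 and Rhag at 0.23. The erythroid mean was higher by 0.13, and by 0.08 (SE 0.05) without wild type replicate 3. For both lists the adjusted p was 0.701 with an estimated correlation, and 2 of 3 knockout arrays had a mean above all wild types. Capicua targets were above 0 in 21 of 21 (camera adjusted p = 2.92e-05, and adjusted p = 0.328 with an estimated correlation). Values were 0.25 for Dusp4, 0.17 for Etv1, 0.13 for Etv5 and 0.11 for Spry1, and 3 of 3 knockout arrays lay above all wild types (exact permutation p = 0.1, the smallest these arrays can give). Neutrophil genes were below 0 in 20 of 20 (camera adjusted p = 0.00280, and adjusted p = 0.701 with an estimated correlation), with Il1r2 at -0.45 and Lcn2 at -0.30. Wild type replicate 3 had a mean neutrophil level of 10.56, and the other arrays of this set lay between 8.88 and 9.32. Without that array the neutrophil list passed in the opposite direction, its mean higher by 0.26 (SE 0.08). Cell cycle genes were below 0 in 23 of 25 (camera adjusted p = 0.00136, and adjusted p = 0.701 with an estimated correlation), with Cenpe at -0.12 and Kif11 at -0.10. In none of these lists did a member pass over all genes or adjusted over the list alone. Capicua targets were a subject of the study, so their direction is no independent evidence.

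Further lists above 0 in the Atxn1 knockout were growth factor signalling by FGF, PDGF and Hedgehog (19 of 21 members, camera adjusted p = 0.00114), with Shh at 0.13 and Ptch1 at 0.09, the basement membrane (14 of 17, camera adjusted p = 0.00136), with Fras1 at 0.18, and alveolar type 1 cells (13 of 14, camera adjusted p = 0.00280), with Hopx at 0.13. T and natural killer cells (12 of 16, camera adjusted p = 0.00300, Cd3g at 0.30), smooth muscle (14 of 16, camera adjusted p = 0.00675, Mustn1 at 0.20) and Notch signalling (13 of 17, camera adjusted p = 0.0279, Notch4 at 0.12) also passed. So did immediate early genes (15 of 20, camera adjusted p = 0.0286, Nr4a1 at 0.29), mast cells (7 of 10, camera adjusted p = 0.0342, Mcpt4 at 0.28) and macrophages (15 of 21, camera adjusted p = 0.0437, Csf1r at 0.17). Downward lists were cholesterol synthesis (12 of 15 below 0, camera adjusted p = 0.0295, Insig1 at -0.10), club and secretory airway cells (9 of 13, camera adjusted p = 0.0437, Scgb3a1 at -1.04 and Muc5b at -0.36) and cartilage (11 of 12, camera adjusted p = 0.0437, Chad at -0.17). For each of these 12 lists the adjusted p was 0.701 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. Metalloproteinases were above 0 in 8 of 20, with a median of -0.03 and none passing either way (camera adjusted p = 0.813, and adjusted p = 0.931 with an estimated correlation). Mmp12 had 0.30 and Mmp3 -0.14. Of 52 lists, 12 passed upward and 5 downward, and none by fry, by the permutation test or with an estimated correlation, and 4 of the 10 splits of these 6 arrays gave as many. Without wild type replicate 3, 14 passed upward and 0 downward, and 6 of them had passed with all arrays, neutrophil genes in the opposite direction. Over the fits without 1 array, 8 to 14 passed upward and 0 to 8 downward. Leaving out single arrays ended the calls of all 12 further lists: the highest adjusted p ranged from 0.115 for alveolar type 1 cells (without wild type replicate 1) to 0.939 for club cells (without wild type replicate 3).

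**Figure D3:**
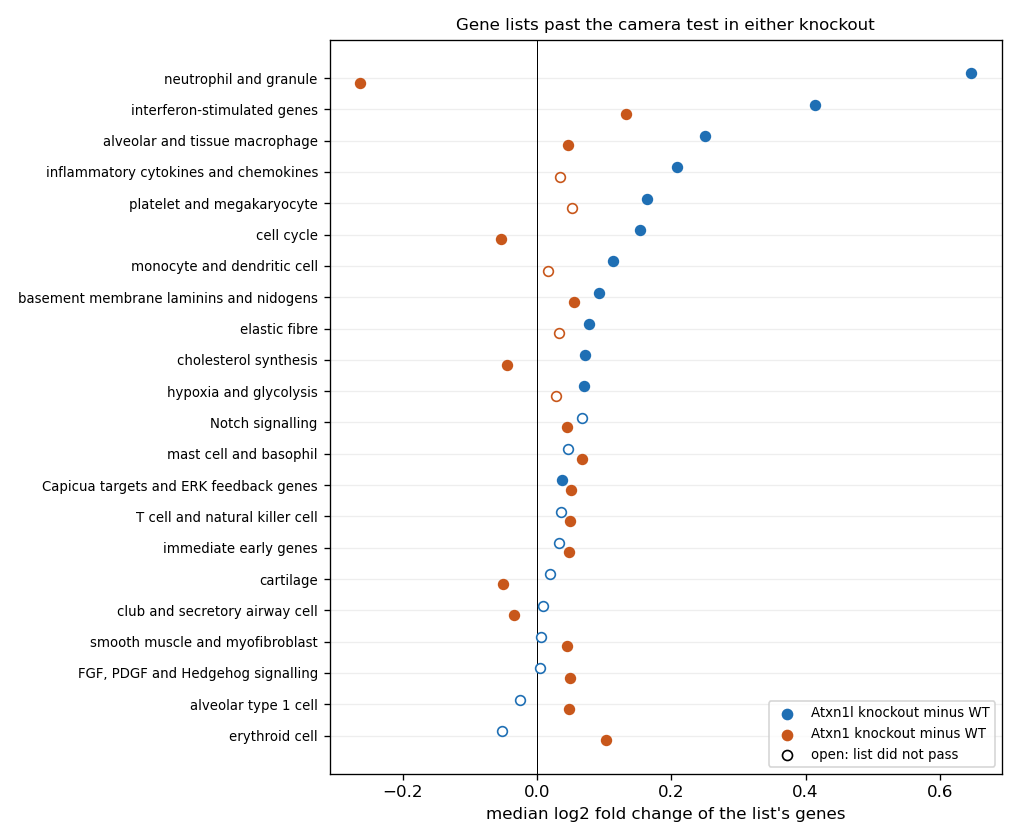
Median log2 change (knockout minus wild type) of the measured genes of each list that passed camera in either knockout. Filled points passed and open points did not. Neutrophil genes have the widest range, 0.65 in the Atxn1l knockout and -0.26 in the Atxn1 knockout, and the sign of the latter rests on wild type replicate 3.

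Set against each other, the knockouts differed in 2 of 21212 probe sets by limma's test of the difference. Atxn1l differed by -2.60 (SE 0.12, adjusted p = 7.01e-08) and Chst4 by -0.67 (SE 0.08, adjusted p = 0.0166), with Chst4 at 0.07 in the Atxn1 knockout. The call of Chst4 was lost in 8 of the 14 fits without 1 array (adjusted p = 0.0520 to 0.109): without Atxn1l knockout replicate 1 or 3, without their wild type replicate 1, 3 or 4 and without any of the 3 Atxn1 knockouts. Its difference lay between -0.71 and -0.61 in all 14. Etv4 was 0.09 in the Atxn1 knockout (difference 0.39, adjusted p = 0.865) and Chil3 0.51 (difference 0.95, adjusted p = 0.999553), so neither was shown to differ. Across 18784 genes the log2 changes of the knockouts had a Pearson r of 0.046 and a Spearman rho of -0.014, where genes are not independent replicates. Leaving out single arrays moved r between -0.15 and 0.29, the latter without Atxn1 wild type replicate 3. An unadjusted p under 0.05 in both knockouts was found for 36 genes, where 17.0 would be expected, and 30 of them had the same direction, 27 upward, a number that 20 of 100 joint splits of the arrays reached. Upward in both were the interferon-stimulated genes Usp18, Ifit3 and Oasl2 and the metalloproteinase gene Mmp12 at that unadjusted threshold. Of the lists, 7 passed camera in both knockouts, 4 of them in the same direction, and none passed in either with an estimated correlation. The tally depends on single arrays. Without Atxn1 wild type replicate 3 the neutrophil list turned direction. The cell cycle, cholesterol synthesis (camera adjusted p = 0.734) and basement membrane lists (camera adjusted p = 0.148) then no longer passed. Of the 4 lists with the same direction, macrophages passed in 2 and the basement membrane in 4 of the 6 Atxn1 fits without 1 array. Capicua targets and the basement membrane each passed in 5 of the 8 such Atxn1l fits. Interferon-stimulated genes passed in all fits of both sets. No list passed a permutation test of the difference between the knockouts after adjustment over 52 lists. The smallest adjusted permutation p, 0.223, was that of the Atxn1 and Capicua complex, which holds the deleted Atxn1l, and the next was 0.808. With so few arrays a single list could not have passed, so this test does not show that the lists were alike.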

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

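The tests of single arrays against the macrophage and interferon genes, those with Xist or blood and those of the genes beside Atxn1l were chosen after the result was seen.

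Macrophage genes of the Atxn1l knockout had 1 array, replicate 1, far from the rest. The gap of the most distant array to the next, as a share of the group's range, was 0.900 for the mean of the macrophage list, 0.935 for C1qb and 0.856 for Msr1 among the 4 knockouts. It was 0.839 for the mean of the inflammatory cytokine list among the knockouts and 0.882 among the wild types. Further gaps were 0.832 for Spred3 in the knockouts and 0.871 for Bub1b and 0.867 for Insig1 in the wild types. Of 122 groups of arrays examined, 8 had such a gap, and 6.1 would be expected by chance.

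Higher macrophage and interferon genes in the Atxn1l knockout were weighed together: against 1 array as the whole source, the macrophage mean was still higher by 0.24 (SE 0.04) and the interferon mean by 0.38 (SE 0.16) without knockout replicate 1, the array with the highest mean of both lists, and the interferon mean by 0.38 (SE 0.17) without replicate 4, the next highest. Against an uneven share of the sexes, the shifts were 0.43 (SE 0.09) and 0.42 (SE 0.17) with the Xist level as a covariate. The only knockout with low Xist is replicate 1, so this fit cannot separate sex from that array. On arrays with high Xist alone, the macrophage means were 8.96, 8.98 and 9.01 in the knockouts and 8.72 and 8.65 in the wild types. The interferon shifts are not large against their SE and settle neither 1 array nor sex as a source of those genes. Against more whole blood in the knockout lungs, as a source of the macrophage genes, the erythroid mean differed by 0.020 (SE 0.04). Other genes carried by blood did lie higher, platelet genes by 0.26 (0.12 without knockout replicate 1) and neutrophil genes by 0.70 (0.37 without it), so blood cells other than red ones are not excluded. More or more active macrophages in lungs without Atxn1l may be a hypothesis to follow, found and tested on the same arrays. Litter, which the labels do not give, and chance over 52 lists stay open, as do 1 array and sex for the interferon genes.

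Chst4 and Atxn1l had effects that differed between the knockouts by limma's test, by -0.67 and -2.60 on the log2 scale. Atxn1l is the gene deleted in 1 of them, and the call of Chst4 was lost in 8 of the 14 fits without 1 array (highest adjusted p = 0.109). For Chst4, flanking DNA from the strain of the stem cells could act on a neighbour, and so could the targeted allele itself. Of the genes within 10 Mb 1 of 183 passed, against 7 of 18591 others (Fisher's exact p = 0.0754), and the 20 nearest named genes had an unadjusted p under 0.05 in 3 cases with Fisher's exact p = 0.246. Chst4 is the 1 gene of the first test and 1 of the 3 of the second, beside Hp and Pkd1l3, and without it 0 of 182 and 2 of 19 remain (Fisher's exact p = 1 and 0.677), so neither test decides, and these explanations and an effect of the lost protein cannot be told apart for Chst4.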

How the results depend on the processing

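The Xist covariate and the permutation test of lists were chosen after seeing the data. Changed probe sets in the Atxn1l knockout numbered 9 with no alternative, 2, Atxn1l and Chil3, with the replicate number as a block and 1, Msr1, without dim probe sets, a filter that leaves out 7 of the 9 untested (Atxn1l, Chil3, Etv4, Hal, Macc1, Chst4 and Cd209a) and under which Pla2g7 had an adjusted p of 0.106. The other settings gave 8 to 12. Pairing was examined on deviations, each probe set's level minus the mean of its group. In these, 3 of the 7 knockout arrays correlated best with the wild type of their number. The r between the deviations of same-numbered arrays was -0.417 to 0.421. The numbers were therefore not taken as pairs, and pairing was not ruled out. Leaving out 1 array gave 2 to 25: 16 without knockout replicate 1, 19 without 2, 4 without 3 and 2 without 4, and 3 without wild type replicate 1, 2 without 2, 4 without 3 and 25 without 4. In the Atxn1 knockout array weights called 1, and every other setting 0. Probe sets that differed between the knockouts numbered 2, but 1 with the block, 1 without dim probe sets (Chst4 is left out untested), 4 with array weights, 21 by a z test of both estimates and 1 to 2 without single arrays, Chst4 being lost in 8 of 14 fits and, at an adjusted p of 0.230, with the block. Lists in the Atxn1l knockout numbered 12, but 0 with an estimated correlation, 1 by fry and 0 by the permutation test, and 9 to 13 without single arrays. Lists in the Atxn1 knockout numbered 17, but 0 by each of these 3, 11 with joint quantile normalization, and 11 to 19 without single arrays, the lowest without knockout replicate 3. Without wild type replicate 3 none of the 14 was lower.

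The correlation of the knockouts, 0.046, was -0.014 by Spearman and 0.366 over changed genes only. Those were the 9 genes called in the Atxn1l knockout, the deleted Atxn1l among them, as none was called in the Atxn1 knockout. An r over so few genes, chosen by 1 of the comparisons, does not show that changed genes agree between the knockouts. It lay between -0.152 and 0.292 without single arrays, negative without Atxn1l knockout replicate 4 (-0.0271), its wild type replicates 2 (-0.00592) and 3 (-0.00196), Atxn1 knockout replicates 2 (-0.0663) and 3 (-0.0165) and their wild type replicates 1 (-0.00540) and 2 (-0.152). The change of Atxn1 in its own knockout, 0.01, reversed to -0.0068 with joint quantile normalization and lay between -0.035 and 0.074 without single arrays. Negative values were -0.0022 without knockout replicate 3, -0.035 without wild type replicate 1 and -0.0097 without 3. Atxn1l in the Atxn1 knockout reversed to -0.0016 with quantile normalization, -0.0018 with the Xist covariate, -0.0034 without knockout replicate 3 and -0.0074 without wild type replicate 2, with 0.042 the highest value without an array. Within 10 Mb of Atxn1, 2 of 140 genes (1.43%) had an unadjusted p under 0.01 (Fisher's exact p = 0.0295), against 0 at the adjusted threshold, and the p was 0.109 within 5 Mb and 0.0950 within 20 Mb. The filter leaves out genes by construction, and the cause of the other shifts was not tested. Each of the 9 changed genes kept its direction in all fits. Past the threshold in 7 settings other than the dim filter and leaving out arrays were Atxn1l and Chil3 in 7, Msr1, Etv4, Chst4 and Cd209a in 6 and Pla2g7, Hal and Macc1 in 5, and the highest adjusted p over all fits was 0.243, for Pla2g7. Among these 7, averaging the probe sets of a gene all but repeats the main fit, as only 2 genes had more than 1 probe set. Signal over background, which limits dim genes, was not analysed here.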

Other observations

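The gene families below were chosen after their values were seen, as were the blood tests of the neutrophil arrays and the counts of splits for the correlation and for the difference without the deleted genes. Genes of MHC class I, which present peptides to T cells, were above 0 in 18 of 22 members in the Atxn1l knockout, with a mean change of 0.33 (exact permutation p = 0.0857). In the Atxn1 knockout 17 of 22 were above 0, with a mean of 0.18 and 3 of 3 knockout arrays above all wild types (exact permutation p = 0.1, the smallest these arrays can give). Guanylate-binding proteins, induced by interferons, had a mean of 0.38 in the Atxn1l knockout (11 genes, exact permutation p = 0.143) and 0.43 in the Atxn1 knockout (exact permutation p = 0.2). The Ifi200 family had a mean of 0.62 in the Atxn1l knockout (7 genes, exact permutation p = 0.0571) and 0.13 in the Atxn1 knockout (exact permutation p = 0.8). MHC class II genes had 0.08 and 0.03 (10 genes, exact permutation p = 0.371 and 0.6).

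Chitinase-like proteins, the family of Chil3, were above 0 in 7 of 7 members in the Atxn1l knockout, with a median of 0.15 and a mean of 0.33 (exact permutation p = 0.0286, the smallest these arrays can give). Without Chil3, for which the family was picked, the other 6 had a mean of 0.14 (exact permutation p = 0.171), so no shift of the family beyond Chil3 was shown. In the Atxn1 knockout the mean was 0.07 (exact permutation p = 0.8). The CD209 family, to which Cd209a belongs, had a median of -0.0037 and a mean of -0.10 in the Atxn1l knockout (7 genes, exact permutation p = 0.0857). Without Cd209a, for which it was picked, the other 6 had a mean of -0.02 (exact permutation p = 0.629). The whole family had a mean of -0.06 in the Atxn1 knockout (exact permutation p = 0.7). Members of these families resemble each other in sequence, and probes shared between them were not analysed here.

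Neutrophil genes were high on 1 array of each set: Atxn1l knockout replicate 1 exceeded the other arrays of its set by 1.51 in the mean of the neutrophil list, and wild type replicate 3 of the Atxn1 set by 1.48. More whole blood on these arrays would raise erythroid genes alike, but their excess was 0.11 (SD 0.05) and -0.19 (SD 0.07). Platelet genes, also of blood, had an excess of 0.62 (SD 0.11) on the first and 0.13 (SD 0.12) on the second, so blood cells other than red ones are not excluded. Genes of the same level do not decide on a distorted array: 400 of them had a median deviation of 0.017 on the first and 396 of -0.025 on the second, but quantile normalization holds this median near 0 on every array (at most 0.034 and 0.081 on any array of these sets). A distorted array and neutrophil numbers that vary between pups therefore both stay open, and no biological explanation was tested. Each of these arrays was also the only one of its sex by Xist in its group, with a low level on the first and a high one on the second. Sex can therefore not be told apart from either array.

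Chance was examined by regrouping the arrays of a set. In the Atxn1l knockout, 1 of 35 splits, the real one, gave 9 or more changed probe sets, and the highest other gave 0. The deleted Atxn1l is among the 9 and by itself puts the real split above the others, and the splits were not counted again without it. The other 8 calls were made only in the real split, but 1 of 35 is the smallest share these splits can give. They also ignore the pairs in which the mice were collected, and 2 calls remained with the replicate number as a block. Chance is therefore not excluded for the genes besides Atxn1l. For its gene lists, 21 of 35 splits gave 12 or more, with a highest of 23, so chance is not excluded for the number of lists. Splits of mixed genotype that call as many lists point to a structure of the arrays that camera's preset correlation does not take up, as the median estimated correlation of these 12 lists was 0.480. In the Atxn1 knockout the 10 possible splits are too few: the real one gave 0 changed probe sets (10 of 10 splits as many, highest other 5) and 17 lists (4 of 10 as many, highest other 20). For the difference between the knockouts, 3 of 100 drawn splits gave 2 or more probe sets, highest other 3. That count includes the deleted Atxn1l, which differs by construction, so it says nothing beyond the deletion. Besides the deleted genes the real split gave 1, Chst4, a call lost in 8 of the 14 fits without 1 array, and 4 of 100 splits gave 1 or more, highest other 2, a share only just under 0.05. The 4 include the real split. The draw also allowed splits that keep the real Atxn1l groups and regroup only the Atxn1 arrays. That share is therefore no clean rate of chance and does not decide on Chst4. An absolute r of 0.046 or more was found in 86 of 100 splits, highest 0.450, and 30 or more genes in the same direction in 20 of 100, highest 110. Chance is excluded for neither the correlation nor the overlap.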
